A study of Mus musculus with 8 samples.

How the data were processed

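RNA was measured in 8 libraries of sorted mouse Kupffer cells, 4 WT and 4 Vsig4 KO. Per the labels' protocols, livers with B16F10 metastases were digested with collagenase IV and DNase I, red cells were lysed, and DAPI-negative CD45-positive Tim-4-positive cells were sorted before library preparation with a VAHTS Universal V8 kit. Per the submitters' processing notes, HTSeq 0.6.1 and the mm10 build were used; the aligner, strand setting and annotation release are not given in the sources used here. Genes on opposite strands that overlap, and near-identical copies, could therefore not be told apart with certainty.

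The deposited table gives raw counts per gene for each library, per the file headers, and the authors' FPKM values beside them. The deposited FPKM values matched the count divided by exonic gene size and column total, on the FPKM scale, within 0.015 for 100% of genes in each library. The deposited table also gives exonic sizes and gene positions as other numbers. Of 52073 gene identifiers shared with GENCODE M21 (GRCm38), only 1472 had the same position, so the coordinates are not those of mm10 in that release and are given as deposited, without a build. The table had 56691 genes. All columns of per-library values were mapped to samples: the column letter K was read as KO, the letter C as the WT control, and the digit as the number in the title.

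Genes were kept by filterByExpr, which left 15870, and libraries were scaled by TMM. KO was compared with WT in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. SEs of log2 fold changes were derived from the unshrunken coefficient and the F statistic. The design named limma on log2(FPKM + 1) as the test unless the file held counts, and edgeR where it did; the file held counts. CPM values use TMM-scaled library sizes, and list means use log2 CPM with a prior count of 2. The biological coefficient of variation was 33.3% without a block.

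Gene lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists, and beside it with an estimated correlation and with fry, whose directional p was used. Single values were compared by exact permutation over 70 splits, for which 0.0286 is the smallest p, differences within pairs by sign flips, chosen after the data were seen, and correlations by enumerating 40320 pairings. The lists, the rule for the genes named and the alternatives except those given last were fixed before the data were examined; the ribosomal, mitochondrial and oxidative phosphorylation lists are symbol patterns. The rule took Vsig4, then, of genes past the threshold whose genotypes did not overlap, with a mean FPKM of at least 1 in the higher genotype and no provisional, pseudogene or receptor segment symbol, the 12 largest changes in each direction; with fewer than 10 in a direction these were filled to 8 by the smallest p. From each list it took up to 4 members past the threshold, or the 2 most expressed. The rule was also applied to the blocked fit. Some members that the rule names are not reported here.

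The genotypes share the numbers 1 to 4. Deviations from the genotype means, over all tested genes, correlated between same-numbered libraries at 0.561, 0.544, 0.660 and 0.290 for numbers 1 to 4. All 4 are above 0.1, so the numbers were taken to pair the libraries and blocked values are given beside results they change. The pairing comes from these values, not from the labels. In both genotypes numbers 1 and 2 had less melanoma RNA than 3 and 4. The correlations may therefore come from that shared gradient and not from pairs of animals. Blocked and paired results hold only if the pairing is right. WT 2 correlated best with KO 1, WT 4 with KO 3, KO 1 with WT 2 and KO 4 with WT 3. No pair of libraries of a genotype agreed within sampling noise: the chi-square per degree of freedom of their counts was at least 10.1.

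Depth was 15264043, 19445494, 15795716 and 15282774 counts in WT 1 to 4 and 18221395, 19513844, 16994406 and 17873668 in KO 1 to 4. Mitochondrially encoded genes took 4.07% to 8.16% of counts and the most abundant gene 1.87% to 3.57%. A count of 0 allows up to 3 counts, 0.154 to 0.197 CPM, for counting error only. The scripts were tested on simulated data with the means, library sizes and spread of the 15870 genes of this comparison. Genes were drawn independently, and effects of the replicate number were built in for the blocked fit. The genes counted for recovery were drawn from those with an average log2 CPM above 2. Recovery of less expressed genes, among them some named below, was therefore not tested. The real libraries share a strong common axis, so the simulated rates of false calls do not carry over to the blocked calls. Without the block 44% of 2-fold and 87% of 4-fold changes were recovered, with 9 false calls among 141. With the block it was 87% and 100%, with 12 among 212. DESeq2 (1.42.0) recovered 74% and 94%, with 59 false calls among 233. Limma, run there on log2(CPM + 1) and not on FPKM, recovered 38% and 87%, with 12 among 138. Alternatives were the size factors, the filters, DESeq2, limma on FPKM with other pseudocounts, filters, scalings, variance models and array weights, the replicate block, and leaving out each library. The melanoma list as a covariate, leaving out WT 1, WT 2 and KO 3, leaving out pairs under the block and scaling to the Kupffer list were chosen after the data were seen. WT 1 and WT 2 had the least melanoma RNA of the WT libraries and KO 3 the most of the KO libraries. Leaving them out sets WT 3 and WT 4 against KO 1, KO 2 and KO 4, and removes the melanoma difference by selection. With the covariate or with libraries left out, camera was run at the preset correlation only. The covariate was the mean log2 CPM of the melanoma list, entered as a linear term. That mean was 4.76, 8.26 and 9.42 in WT 2, WT 3 and KO 3, and the Kupffer mean 9.91, 9.19 and 7.94. The fall was thus not a straight line, so the covariate may not match melanoma content fully, chiefly in KO 3.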

Results

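Kupffer cells, the resident macrophages of the liver, were sorted a week after the mice had received B16F10 melanoma cells, a mouse tumour line that formed metastases in the liver. The sort gate kept living cells that carried the leukocyte protein CD45 and the Kupffer cell receptor Tim-4. Bulk RNA-seq was available for 4 libraries from wild-type (WT) mice and 4 from mice without Vsig4 (KO). Vsig4 encodes a complement receptor and immune checkpoint of tissue macrophages, and the series names the T cell protein CD5 as its interaction partner. Total counts ran from 15264043 in WT 1 to 19513844 in KO 2, and 22323 to 23483 genes had at least 1 count in a library. The labels do not say that the 4 libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries, which may be in part technical. The single comparison of the design was KO against WT. Values below are means ± SD over n = 4 libraries per genotype in CPM (counts scaled to a common library size), and log2 fold changes are KO minus WT ± SE.

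Vsig4 transcripts were nearly absent from all 4 KO libraries. Vsig4 (ENSMUSG00000044206, X chromosome, 95290809 to 95337044, minus strand in the deposited coordinates, whose build is not given) had 22498 to 46735 counts in the WT libraries and 2 to 9 counts in the KO libraries. That is 2136 ± 732 CPM in WT and 0.282 ± 0.166 CPM in KO. The log2 fold change was -12.89 ± 0.531, or a 7594-fold lower level (edgeR adjusted p = 5.35e-05), and the exact 2-sided permutation test gave p = 0.0286, the smallest value possible with 4 against 4. The libraries labelled KO and WT thus differed in the targeted gene in the direction of their labels.

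**Figure D1:**
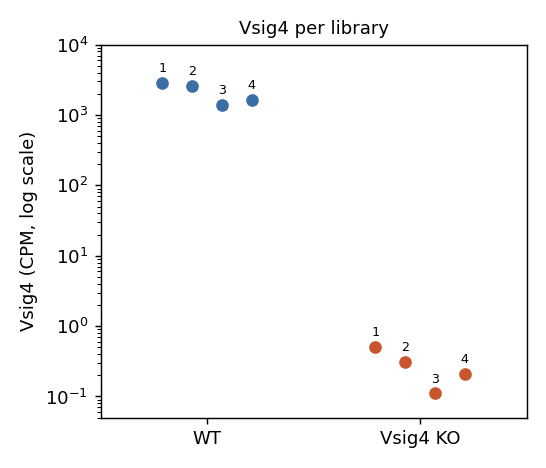
Vsig4 in each library, in CPM on a log axis, for WT (left) and Vsig4 KO (right); each point is 1 library with its number. The WT libraries lie between 1392 and 2890 CPM and the KO libraries between 0.111 and 0.501 CPM.

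Vsig4 was the only one of 15870 genes that passed the adjusted threshold of 0.05 in the comparison of KO with WT. No gene was higher in KO in edgeR, while 671 genes were higher and 723 lower at an unadjusted p under 0.05; limma on log2(FPKM + 1) also called 0 higher genes and DESeq2 called 30. DESeq2 called 66 genes in all and limma with array weights 31. With the replicate number as a block, 2220 genes passed, 1425 of them higher and 795 lower in KO. That blocked count was 207 without pair 1, 2 without pair 2, 1 without pair 3 and 2229 without pair 4, so it depended on which pairs were in the fit. The pairing was read from these data and not from the labels, so blocked calls hold only if it is right.

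Apart from Vsig4, no gene passed without the block, and the genes with the smallest p among those with separate groups are given as values. Dynlt1b, a dynein light chain, had 10.01 ± 1.19 CPM in WT and 26.5 ± 4.85 CPM in KO (log2 fold change 1.41 ± 0.173, adjusted p = 0.141). It belongs to a family with near-identical copies, which makes its level uncertain. Mmp12, the macrophage elastase, had 53.8 ± 18.9 CPM in WT and 145 ± 36.8 CPM in KO (log2 fold change 1.43 ± 0.293, adjusted p = 0.492). The others with higher values in KO were Prokr1 (1.03 ± 0.207), the oxysterol receptor Gpr183 (0.73 ± 0.154), the co-chaperone Stip1 (0.60 ± 0.132), Arhgap39 (0.59 ± 0.119), the small GTPase Rap2a (0.57 ± 0.119) and Gdpd1 (0.56 ± 0.119), all log2 fold changes. Lower values in KO were found for Mgst1, a microsomal glutathione transferase, with 53.6 ± 4.51 CPM in WT and 29.3 ± 4.36 CPM in KO (log2 fold change -0.87 ± 0.130, adjusted p = 0.449). Lrmda (-2.72 ± 0.500), the adaptor Stap2 (-1.59 ± 0.276), Igfbp7 (-1.36 ± 0.285), the glutamate transporter Slc1a3 (-1.28 ± 0.274), Ppp1r12b (-0.58 ± 0.114) and Zfp945 (-0.52 ± 0.112) followed on the log2 scale. The groups did not overlap in 5.56% of tested genes, where chance gives 2.86% on average over splits. Genes varied together in these libraries, so the share in a single split can lie far from that average. The share was not computed for other splits, so no excess is claimed.

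With the block, the same rule named 12 higher and 12 lower genes. Of the genes that qualified, the largest rises were in Ddias (blocked log2 fold change 1.55 ± 0.333), Mmp12 (1.46 ± 0.261), Dynlt1b (1.39 ± 0.152), the replication licensing factor Cdc6 (1.09 ± 0.121) and Slfn3 (1.08 ± 0.212), followed by Camk2b, Rad54b, Gpr19, Lrr1, Prokr1, Mras and Cdk5rap1. After Vsig4, the largest fall was in Cd5, a T cell surface protein, with 6.35 ± 3.91 CPM in WT and 0.407 ± 0.813 CPM in KO (blocked log2 fold change -4.63 ± 1.20, adjusted p = 0.0440; -3.95 ± 1.28, adjusted p = 0.492, without the block). Cd5 had no counts in KO 1, KO 2 and KO 3 and 31 counts in KO 4. Lrmda (-2.74 ± 0.540), the interferon-inducible Ifi208 (-2.73 ± 0.481), Ccdc80 (-1.68 ± 0.319) and Stap2 (-1.61 ± 0.307) came next, then Gsta3, Fam3b, Olfr56, Rgn, Igfbp7 and Casp12.

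Cd5 transcripts were set against those of Cd3e, Cd3d and Cd3g, chains of the T cell receptor complex, since the Tim-4 gate should leave few T cells and their number could differ. Cd5 had 16.8, 17.4, 18.1 and 13.9 counts per 100 Cd3 counts in WT 1 to 4, and 0, 0, 0 and 12.1 in KO 1 to 4 (exact permutation p = 0.0286). The rule names only genes whose genotypes do not overlap, so this p was largely fixed by that choice. KO 4, at 12.1, lay close to WT 4, at 13.9. A count of 0 allows up to 0.258, 0.349 and 0.980 per 100 Cd3 counts in KO 1, KO 2 and KO 3. Its neighbour Cd6, chosen after its values were seen, had 17.3 ± 1.20 per 100 Cd3 counts in WT and 32.5 ± 2.88 in KO (exact permutation p = 0.0286).

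**Figure D2:**
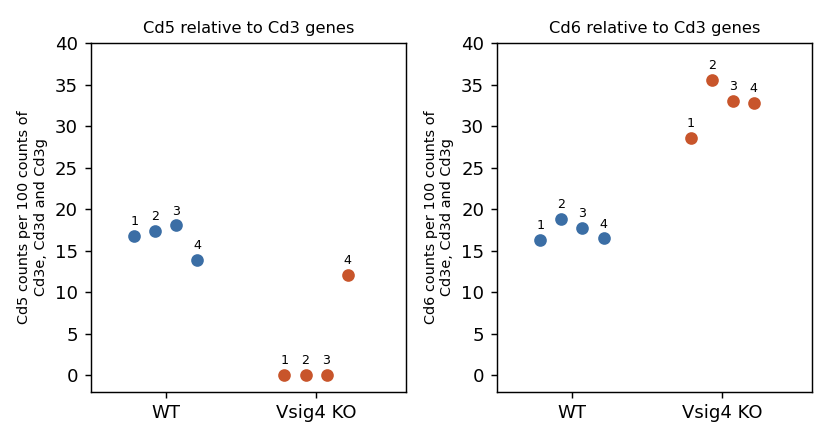
Counts of Cd5 (left) and Cd6 (right) per 100 counts of Cd3e, Cd3d and Cd3g (y axis) in WT and Vsig4 KO; each point is 1 library with its number. Cd5 is at 0 in KO 1 to 3 and 12.1 in KO 4, and Cd6 is higher in each KO library (28.6 to 35.6) than in any WT library (16.3 to 18.8).

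Melanoma transcripts were present in every library and in unequal amounts. The 10 melanoma genes fixed in advance, which include the pigment genes Pmel, Tyrp1 and Dct, summed to 573, 507, 5676 and 4853 CPM in WT 1 to 4 and to 2565, 3661, 12682 and 6600.0 CPM in KO 1 to 4. The mean was 2902 ± 2749 CPM in WT and 6377 ± 4536 CPM in KO (exact permutation p = 0.229 on the log2 scale). Within the pairs of equal number the sum was higher in KO in 4 of 4 (mean log2 difference 1.65 ± 1.07; exact sign-flip permutation p = 0.125, the smallest possible with 4 pairs). The summed Kupffer genes were at 28593 ± 7940 CPM in WT and 18789 ± 7674 CPM in KO (exact permutation p = 0.171), lower in KO in 4 of 4 pairs (exact sign-flip permutation p = 0.125). Over the 8 libraries the 2 sums were inversely related (Pearson r = -0.966, permutation p = 4.96e-05, adjusted p = 0.000198; Spearman rho = -0.976, permutation p = 0.000397, adjusted p = 0.00159; 4 relations in the family). The relation held without KO 3 and WT 2, the libraries farthest from the median melanoma content (r = -0.937). Both sums are scaled to the counts of the same library, so more melanoma RNA in itself lowers the Kupffer sum. The permutation p does not allow for that and shows no more than such mixing. Hepatocyte sums showed no such relation to melanoma sums (Pearson r = -0.156, permutation p = 0.676; Spearman rho = -0.167, permutation p = 0.703; r = 0.113 without KO 3 and WT 2). No batch was named in the labels; the first principal component held 64.7% of the variance and followed the mean log2 CPM of the melanoma list (Pearson r = 0.977).

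**Figure D3:**
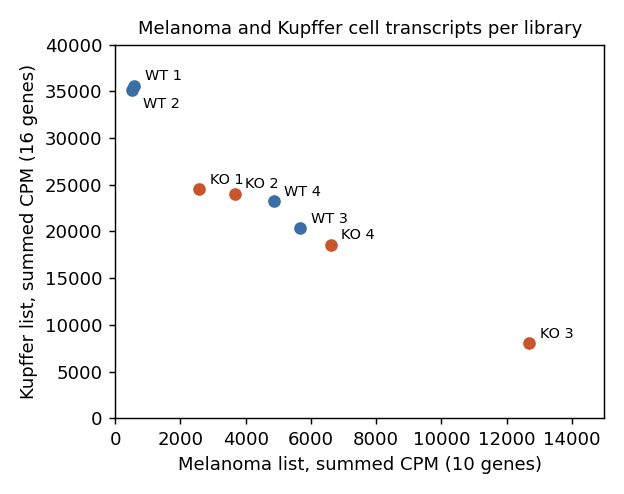
Summed CPM of the 10 melanoma genes (x axis) against the 16 Kupffer genes (y axis); each point is 1 library with its number, WT in blue and KO in orange. WT 1 (573 and 35617 CPM) and KO 3 (12682 and 8017 CPM) lie near opposite ends of the inverse relation.

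Fixed gene lists were then compared between genotypes. Some lists share members, so their results are not independent. Timd4, Marco, Cd163 and Clec4f are in the Kupffer and scavenger lists, and Slc40a1, Cd163 and Spic in the Kupffer and iron lists. C6 is in the Kupffer and complement lists, Il10 in the coinhibition and alternative activation lists, and Cxcl9 and Cxcl10 in the interferon gamma and chemokine lists. Camera with its preset correlation called 27 of 35 lists, 6 higher and 21 lower in KO; with an estimated correlation or with fry it was 0 of 35, with and without the block. Without the block no list member passed over all genes. Adjusted over the list alone, 1 lipid-associated macrophage gene (higher), 6 stellate cell genes (lower) and 2 coinhibition genes (lower) passed, and none in the other lists. Counts of members given below for the block are first those adjusted over all genes and then those adjusted over the list alone. Because melanoma content differed between libraries, each list is also given with its median when the melanoma list was a covariate. That covariate is a linear term in the list's mean log2 CPM and may not match melanoma content fully. Some are also given without WT 1, WT 2 and KO 3, the WT libraries lowest and the KO library highest in melanoma content. That choice, made after the data were seen, removes the melanoma difference by selection and cannot test lists that follow melanoma content. In these fits, and with single libraries left out, camera was run only at its preset correlation. Calls there lack the check that left 0 of 35 lists in the main fit. With the block camera kept 26 of the 27 calls and lost that of the erythroid list (adjusted p = 0.0759).

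**Figure D4:**
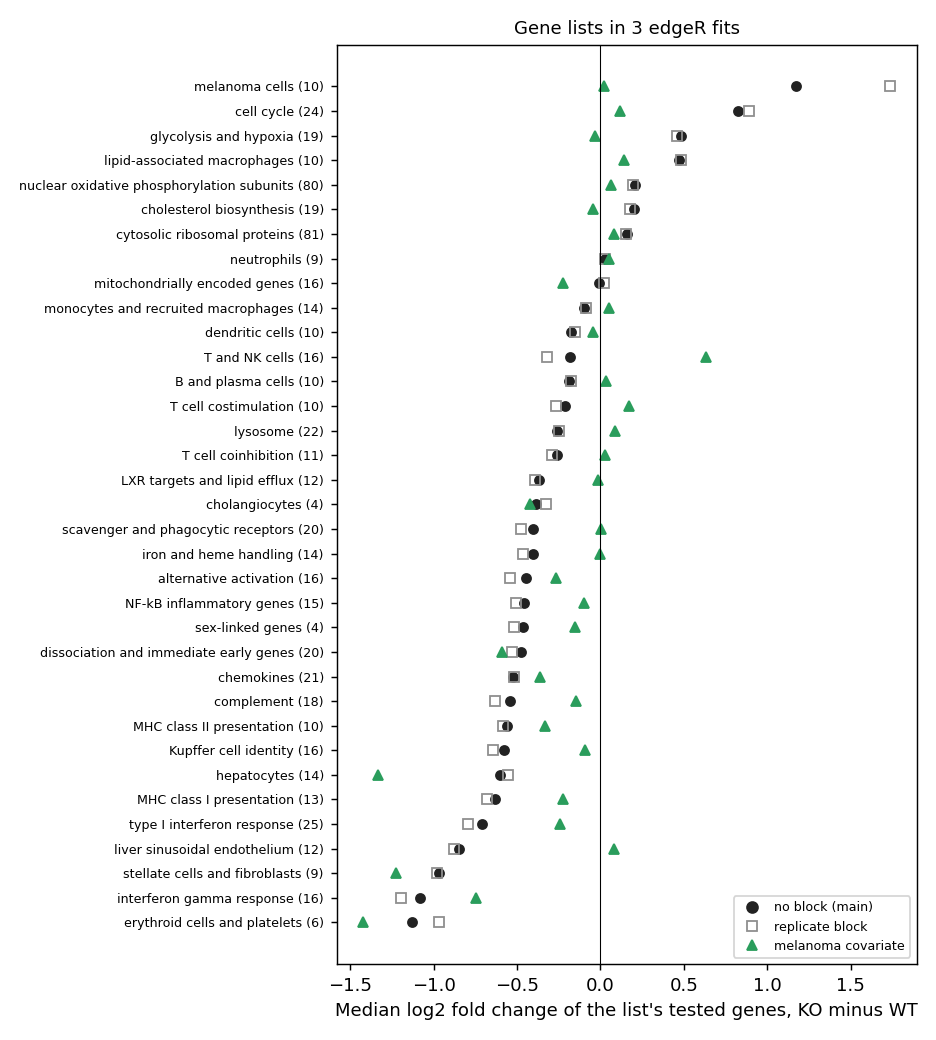
Median log2 fold change (x axis, KO minus WT) of each fixed list, with the number of tested genes in brackets, in the fit without a block (black circles), with the replicate block (open squares) and with the melanoma list as covariate (green triangles). With the covariate the melanoma list goes from 1.17 to 0.024 and the Kupffer list from -0.58 to -0.095, and the interferon gamma list from -1.08 to -0.74.

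Interferon-stimulated genes had lower values in KO. All 16 interferon gamma response genes had lower values in KO, with a median log2 fold change of -1.08 (camera adjusted p = 3.12e-14, and adjusted p = 0.437 with an estimated correlation). With the block, 13 members fell, 16 adjusted over the list alone. Irf1, a transcription factor of the interferon response, had 286 ± 59.6 CPM in WT and 142 ± 50.6 CPM in KO, the guanylate-binding proteins Gbp2 and Gbp3 had 182 ± 65.2 CPM in WT and 85.5 ± 44.0 CPM in KO and 278 ± 94.1 CPM in WT and 142 ± 71.1 CPM in KO, and the T cell attractant Cxcl9 had 105 ± 45.2 CPM in WT and 43.2 ± 32.0 CPM in KO. The type I interferon list had lower values in all 25 members and a median of -0.71 (camera adjusted p = 1.76e-13, and adjusted p = 0.464 with an estimated correlation). Of these, 23 fell with the block, 25 adjusted over the list alone, among them the nucleic acid sensor Zbp1 (105 ± 30.0 CPM in WT and 45.8 ± 22.4 CPM in KO). With the melanoma covariate the medians were -0.74 (camera adjusted p = 4.14e-10) and -0.24 (camera adjusted p = 2.26e-05), and without WT 1, WT 2 and KO 3 they were -0.66 and -0.11 (camera adjusted p = 6.67e-07 and 0.0358). Mean log2 CPM of the interferon gamma list was 6.53 ± 0.529 in WT and 5.25 ± 0.832 in KO (exact permutation p = 0.0571, adjusted p = 0.30 over the 35 lists). Its summed CPM fell with melanoma content over the 8 libraries (Pearson r = -0.737, permutation p = 0.0297, adjusted p = 0.0396; Spearman rho = -0.810, permutation p = 0.0218, adjusted p = 0.0290). Without KO 3 and WT 2 it was r = -0.442, so that relation rested on those libraries. The interferon gamma sum too is scaled to the counts of its library, which the permutation p does not allow for.

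**Figure D5:**
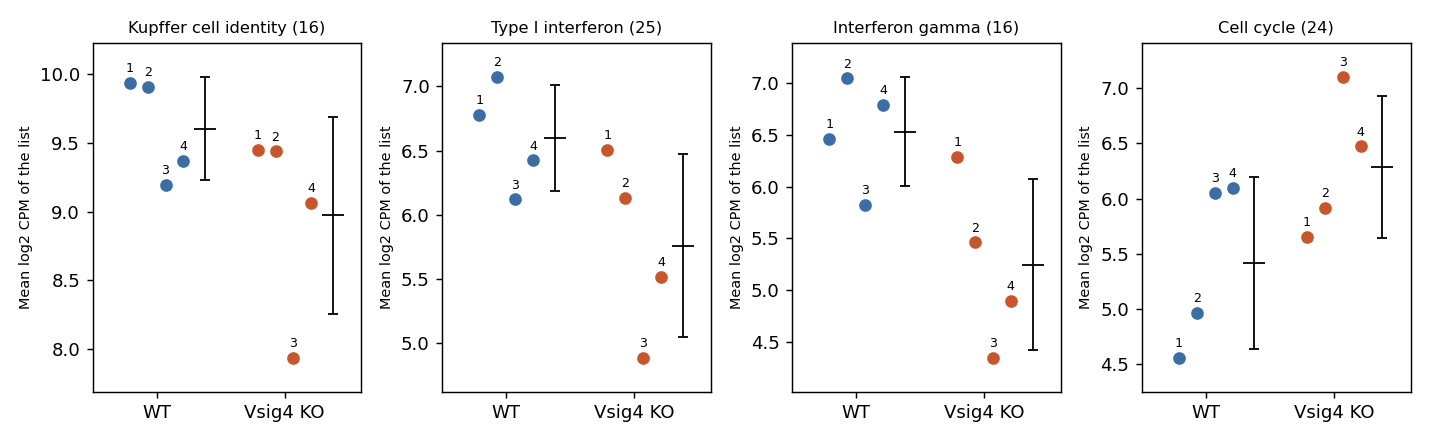
Mean log2 CPM of 4 fixed lists in each library (points, numbered), with the mean and SD of the 4 libraries of a genotype beside them; the number of tested genes is in brackets. KO 3 has the lowest Kupffer value (7.94) and the highest cell cycle value, and the interferon gamma values are 5.83 to 7.05 in WT and 4.34 to 6.29 in KO.

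Antigen presentation genes had lower values in KO. The MHC class I list had a median of -0.63 over 13 genes (camera adjusted p = 7.03e-06, and adjusted p = 0.464 with an estimated correlation), and with the block 10 genes fell, 11 adjusted over the list alone. The peptide transporter Tap1 had 177 ± 39.1 CPM in WT and 101 ± 40.1 CPM in KO and the immunoproteasome subunit Psmb8 had 181 ± 42.8 CPM in WT and 117 ± 43.1 CPM in KO. The MHC class II list had a median of -0.56 over 10 genes (camera adjusted p = 1.06e-05, and adjusted p = 0.464 with an estimated correlation). H2-DMa (232 ± 55.8 CPM in WT and 145 ± 41.3 CPM in KO), Ctss and H2-DMb1 fell with the block, and 6 genes did adjusted over the list alone. With the melanoma covariate the medians were -0.23 (camera adjusted p = 0.0688) and -0.33 (camera adjusted p = 9.29e-04), and without WT 1, WT 2 and KO 3 they were -0.12 and -0.28 (camera adjusted p = 0.499 and 0.00471).

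Ligands and cytokines that restrain T cells had mostly lower values in KO, and costimulators had no common direction. The 11 coinhibition genes had a median of -0.26 (camera adjusted p = 0.0160, and adjusted p = 0.464 with an estimated correlation). The PD-1 ligand Cd274 had 153 ± 49.5 CPM in WT and 75.2 ± 24.2 CPM in KO, and Il10, an anti-inflammatory cytokine, had 18.5 ± 8.05 CPM in WT and 7.85 ± 1.71 CPM in KO. Both fell with the block, as did Vsir, while Cd276 rose (7.81 ± 5.22 CPM in WT and 15.6 ± 10.2 CPM in KO); adjusted over the list alone 3 fell and 1 rose. The costimulation list was not called (10 genes, median -0.21; camera adjusted p = 0.384, and adjusted p = 0.726 with an estimated correlation). With the block its member Il15 fell, and adjusted over the list alone 2 members rose and 5 fell. With the melanoma covariate the coinhibition median was 0.026 (camera adjusted p = 0.237) and the costimulation median 0.17. Without KO 3 the coinhibition median was -0.064 (camera adjusted p = 0.0724), and without WT 1, WT 2 and KO 3 it was 0.075 (camera adjusted p = 0.931).

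Inflammatory and complement genes also had lower values. The NF-kB list had a median of -0.46 over 15 genes (camera adjusted p = 5.00e-05, and adjusted p = 0.464 with an estimated correlation). With the block 6 genes fell, 11 adjusted over the list alone, with the inflammasome sensor Nlrp3 at 106 ± 17.6 CPM in WT and 70.2 ± 20.1 CPM in KO. The chemokine list had a median of -0.52 over 21 genes (camera adjusted p = 6.13e-06, and adjusted p = 0.410 with an estimated correlation). Of these 4 fell with the block, 11 adjusted over the list alone, among them the monocyte attractant Ccl2 (60.6 ± 6.90 CPM in WT and 33.1 ± 11.8 CPM in KO). The complement list had a median of -0.54 over 18 genes (camera adjusted p = 3.04e-05, and adjusted p = 0.464 with an estimated correlation). With the block 7 genes fell, including C4b (1028 ± 274 CPM in WT and 484 ± 239 CPM in KO), C2 and C6, and 1 rose; adjusted over the list alone it was 13 lower and 1 higher. The alternative activation list had a median of -0.45 over 16 genes (camera adjusted p = 9.29e-04, and adjusted p = 0.437 with an estimated correlation), with Klf4, Il10 and Igf1 lower with the block and 6 lower adjusted over the list alone. The 4 medians with the melanoma covariate were -0.10, -0.36, -0.14 and -0.27, and camera called the chemokine (adjusted p = 1.84e-04) and alternative activation lists (adjusted p = 9.29e-04). Without WT 1, WT 2 and KO 3 the complement median was 0.0014 and the NF-kB median -0.042 (camera adjusted p = 0.914 and 0.563). The dissociation and immediate early list, which responds to tissue handling, was also lower in KO (median -0.47; camera adjusted p = 1.06e-05, and adjusted p = 0.464 with an estimated correlation), and remained so with the covariate (-0.59, camera adjusted p = 1.18e-06).

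Kupffer cell genes and phagocytic, lysosomal and lipid genes had lower values in KO. All 16 Kupffer identity genes did, with a median of -0.58 (camera adjusted p = 1.79e-06, and adjusted p = 0.464 with an estimated correlation), and 9 fell with the block, 14 adjusted over the list alone. The C-type lectin Clec4f had 8737 ± 2509.6 CPM in WT and 5376 ± 2193 CPM in KO, and Timd4, which encodes the sorted protein Tim-4, had 705 ± 216 CPM in WT and 452 ± 209 CPM in KO. The scavenger and phagocytic receptors had a median of -0.40 over 20 genes (camera adjusted p = 1.88e-04, and adjusted p = 0.506 with an estimated correlation). Of these 6 fell with the block, 10 adjusted over the list alone, including the scavenger receptor Msr1 (867 ± 232 CPM in WT and 509 ± 191 CPM in KO). The lysosome list had a median of -0.26 over 22 genes (camera adjusted p = 0.0184, and adjusted p = 0.653 with an estimated correlation). With the block 4 fell (Ctsc, Ctsl, Npc2 and Lipa), and 5 fell and 2 rose adjusted over the list alone.

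Iron and heme genes had a median of -0.40 over 14 genes (camera adjusted p = 0.00375, and adjusted p = 0.464 with an estimated correlation). Blvrb and Spic fell and the transferrin receptor Tfrc rose with the block, and adjusted over the list alone 9 fell and 1 rose. The LXR targets had a median of -0.37 over 12 genes (camera adjusted p = 0.0258, and adjusted p = 0.502 with an estimated correlation). The lipid carrier Apoe (9451 ± 2412 CPM in WT and 6100.5 ± 2029 CPM in KO), Apoc1 and Abcg1 fell and Scd2 rose with the block, and adjusted over the list alone 5 fell and 1 rose.

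With the melanoma covariate the Kupffer, scavenger, lysosome, iron and LXR lists were not called, with medians of -0.095, 0.0043, 0.089, -0.0030 and -0.016. Without WT 1, WT 2 and KO 3 the same 5 medians were 0.078, 0.15, 0.20, 0.12 and 0.081, and camera called the scavenger (adjusted p = 0.00110) and lysosome lists (adjusted p = 3.25e-05) higher in KO. The lysosome call was lost without WT 1, WT 2 or KO 3 (medians -0.14, -0.18 and -0.15, adjusted p = 0.242, 0.128 and 0.316). That of the LXR targets was lost without WT 1, WT 2 or KO 3, with smaller medians (-0.26, -0.21 and -0.17, adjusted p = 0.0735, 0.0796 and 0.148), and without KO 1, with a larger one (-0.41, adjusted p = 0.0517).

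Proliferation and melanoma genes had higher values in KO. All 24 cell cycle genes did, with a median of 0.83 (camera adjusted p = 7.97e-10, and adjusted p = 0.464 with an estimated correlation), and 22 rose with the block, 23 adjusted over the list alone. The helicase subunit Mcm2 had 91.8 ± 58.2 CPM in WT and 208 ± 117 CPM in KO. All 10 melanoma genes had higher values, with a median of 1.17 (camera adjusted p = 1.56e-04, and adjusted p = 0.464 with an estimated correlation), and 10 rose with the block, 10 adjusted over the list alone; Pmel, a pigment cell protein, had 493 ± 479.8 CPM in WT and 1132 ± 823 CPM in KO. Cell cycle sums followed the melanoma sums over the 8 libraries (Pearson r = 0.991, permutation p = 9.92e-05, adjusted p = 0.000198; Spearman rho = 0.952, permutation p = 0.00114, adjusted p = 0.00228; r = 0.963 without KO 3 and WT 2). With the covariate the cell cycle median was 0.12 (camera adjusted p = 0.0161). Without WT 1, WT 2 and KO 3 the melanoma list was lower in KO (median -0.29, camera adjusted p = 0.0262) and the cell cycle median was 0.0036 (camera adjusted p = 0.931). As those libraries were lowest in WT and highest in KO for the melanoma list itself, these values do not test how stable the rises were.

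Energy metabolism genes had higher values in KO. Glycolysis and hypoxia genes had a median of 0.48 over 19 genes (camera adjusted p = 0.0148, and adjusted p = 0.599 with an estimated correlation). With the block 8 rose, among them the glycolytic enzyme Eno1 (781 ± 372 CPM in WT and 1366 ± 692 CPM in KO), and adjusted over the list alone 12 rose and 1 fell. The nuclear oxidative phosphorylation subunits had a median of 0.21 over 80 genes (camera adjusted p = 3.36e-06, and adjusted p = 0.502 with an estimated correlation), with 10 higher with the block and 14 adjusted over the list alone. Cholesterol biosynthesis was not called (median 0.20 over 19 genes; camera adjusted p = 0.168, and adjusted p = 0.653 with an estimated correlation), and 1 gene, Sqle, rose with the block by either adjustment. Medians with the melanoma covariate were -0.035, 0.064 and -0.044, and camera called the oxidative phosphorylation list (adjusted p = 0.0161) but not glycolysis (adjusted p = 0.108). The glycolysis call was lost without WT 1, WT 2 or KO 3 (medians 0.35, 0.35 and 0.19, camera adjusted p = 0.0639, 0.0936 and 0.371). Without all 3 the glycolysis median was -0.15 (camera adjusted p = 0.00219), and the oxidative phosphorylation call was lost (median 0.033, camera adjusted p = 0.330).

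Markers of stellate, endothelial, hepatocyte and erythroid cells, which the CD45 and Tim-4 gate and red cell lysis should have removed, had mostly lower values in KO. Stellate cell and fibroblast genes had a median of -0.97 over 9 genes (camera adjusted p = 1.07e-06, and adjusted p = 0.410 with an estimated correlation). The growth factor Hgf (28.1 ± 5.17 CPM in WT and 14.4 ± 3.29 CPM in KO), Ecm1 and Col3a1 fell with the block, and 6 genes did adjusted over the list alone. Sinusoidal endothelial genes had a median of -0.85 over 12 genes (camera adjusted p = 0.00590, and adjusted p = 0.506 with an estimated correlation), with 7 lower with the block and 8 adjusted over the list alone. Hepatocyte genes had a median of -0.60 over 14 genes (camera adjusted p = 0.00280, and adjusted p = 0.506 with an estimated correlation). Albumin, Alb (614 ± 491 CPM in WT and 293 ± 179.9 CPM in KO), Trf and Cyp3a11 fell with the block, and 4 genes did adjusted over the list alone. Erythroid and platelet genes had a median of -1.13 over 6 genes (camera adjusted p = 0.0126, and adjusted p = 0.464 with an estimated correlation), and 0 fell with the block by either adjustment. The 4 medians with the melanoma covariate were -1.23, 0.083, -1.33 and -1.42. With it camera called all but the endothelial list (adjusted p = 0.943). The endothelial call was lost without WT 1 (median -0.30, camera adjusted p = 0.170) or KO 3 (-0.59, 0.0552), the hepatocyte call without WT 3 (0.069, 0.297) or KO 2 (-0.36, 0.0894) and the erythroid call without WT 3 (-0.51, 0.167) or KO 2 (-1.06, 0.0566). Without WT 1, WT 2 and KO 3 the endothelial median was 0.20 (camera adjusted p = 0.109).

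Lymphocyte and macrophage markers differed in direction. Lipid-associated macrophage genes had a median of 0.47 over 10 genes (camera adjusted p = 0.00628, and adjusted p = 0.410 with an estimated correlation) and 0.14 with the melanoma covariate. With the block 6 rose, among them Mmp12, Cd63, Fabp5 and Cd9, and 1 fell, the same numbers as adjusted over the list alone. From the block to the melanoma covariate the log2 fold change of Mmp12 went from 1.46 to 1.21, of Cd63 from 1.39 to 0.10, of Fabp5 from 1.43 to 0.18 and of Cd9 from 0.55 to 0.25. The call of the list held with the covariate (camera adjusted p = 0.0283) and was lost without WT 1, WT 2 and KO 3 (median 0.12, camera adjusted p = 0.109). Gpnmb, also expressed by melanoma cells, had 396 ± 384 CPM in WT and 802 ± 622 CPM in KO. The T and NK cell list had a median of -0.18 over 16 genes (camera adjusted p = 0.0158, and adjusted p = 0.599 with an estimated correlation), with Gzma and Cd5 lower with the block by either adjustment. Its median was 0.63 with the melanoma covariate and 0.76 without WT 1, WT 2 and KO 3, and camera called it in neither (adjusted p = 0.0688 and 0.109). The call was also lost without WT 2, KO 3 or KO 4 (camera adjusted p = 0.327, 0.189 and 0.0738), where the median was above 0 (0.24, 0.063 and 0.074).

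Monocyte genes (median -0.096 over 14 genes, camera adjusted p = 0.385), neutrophil genes (0.029 over 9, adjusted p = 0.730), dendritic cell genes (-0.17 over 10, adjusted p = 0.534), B and plasma cell genes (-0.19 over 10, adjusted p = 0.239) and cholangiocyte genes (-0.39 over 4, adjusted p = 0.299) were not called; with an estimated correlation the adjusted p were 0.653, 0.870, 0.832, 0.653 and 0.506. The neutrophil mean was -0.22, below 0 like camera's direction, while its median was above. Of the monocyte list Plac8 fell with the block, and of the B cell list Ighm; adjusted over the list alone it was 0 and 1, and none passed in the others by either adjustment. Camera called the B cell list without KO 1 (adjusted p = 0.0216) and the cholangiocyte list without WT 4 or KO 3 (adjusted p = 0.0281 and 0.0472). With the melanoma covariate the medians were 0.049, 0.052, -0.042, 0.032 and -0.42.

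Dissociation and immediate early genes, which respond to tissue digestion, had a median of -0.47 over 20 genes (camera adjusted p = 1.06e-05, and adjusted p = 0.464 with an estimated correlation). With the block 11 fell and 1 rose, 14 and 1 adjusted over the list alone; Fos had 1234 ± 199 CPM in WT and 759.7 ± 220.3 CPM in KO, and the covariate median was -0.59. Ribosomal protein genes had a median of 0.16 over 81 genes (camera adjusted p = 2.45e-05, and adjusted p = 0.506 with an estimated correlation), with 5 higher with the block, 0 adjusted over the list alone, and 0.082 with the covariate. Mitochondrially encoded genes were not called (median -0.0098 over 16 genes, camera adjusted p = 0.819, and adjusted p = 0.951 with an estimated correlation). Their median was -0.22 with the melanoma covariate (camera adjusted p = 6.23e-04) and -0.31 without WT 1, WT 2 and KO 3 (camera adjusted p = 3.98e-06), both lower in KO, and without WT 3 it was 0.17 (camera adjusted p = 0.0227); with all libraries the mean was 0.00245, above 0 like camera's direction. Sex-linked genes had a median of -0.47 over 4 tested genes (camera adjusted p = 0.00680, and adjusted p = 0.464 with an estimated correlation; -0.15 with the covariate and -0.045 without WT 1, WT 2 and KO 3, camera adjusted p = 0.237 and 0.627). Ddx3y, a Y-linked gene, had 214 ± 49.2 CPM in WT and 143 ± 50.6 CPM in KO, and Xist had at most 6 counts in any library. Ddx3y fell with the block, and adjusted over the list alone 3 of these genes did.

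Genes close to the targeted locus were compared with the rest of the genome. None of the 73 tested genes within 10 Mb of Vsig4 passed the edgeR threshold (Fisher's exact 2-sided p = 1, as no gene outside the window passed either; 1394 genes had an unadjusted p under 0.05 over all chromosomes), and the same was true for 37 genes within 5 Mb and 102 within 20 Mb. With the block 14 of the 73 passed (19.2%), against 13.96% of the other genes (Fisher's exact 2-sided p = 0.233).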

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

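The tests of explanations for Cd5 were chosen after its values were seen. Of 434 groups of 4 libraries examined for a library apart from the other 3 (list means, depth and named genes), 16 held one, where chance, at about 1 in 20 groups, gives 21.7; 8 of the 16 were in KO 3 and 4 in WT 2.

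Cd5 had 1.627 CPM in KO 4 and no counts in KO 1 to 3. It was the 1 gene of all in the deposited table under 0.3 CPM in KO 1 to 3 and over 2 CPM in each WT library. Those limits were chosen after the values were seen. Vsig4 itself missed them, at 0.501 and 0.306 CPM in KO 1 and KO 2, so being the only gene depends on the limits. Fewer T cells are argued against, as the lowest WT ratio of Cd5 to Cd3e, Cd3d and Cd3g predicts 324.2 Cd5 counts over KO 1 to 3, where none was found. Counts given to an overlapping gene are argued against too, since 0 genes overlap Cd5 in the deposited coordinates (chromosome 19, 10694480 to 10716366, minus strand). A candidate explanation is a variant or disrupted Cd5 locus in these animals: Cd6, 50339 bp away, had another ratio to the Cd3 genes in KO, without overlap (exact permutation p = 0.02857, the smallest possible). That stays open, because KO 4 had a high Cd6 ratio and Cd5 counts as well, and the labels give no Cd5 genotype. Of 48 tested genes within 1 Mb of Cd5, 6 were called with the block, against 2220 of 15870 tested genes, so calls were not in excess around the locus.

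In KO 3, Ccl6 was at 341.2 CPM, Ctsl at 215.9 CPM, Cxcl13 at 42.82 CPM and Dynlt1b at 19.25 CPM, each below the other KO libraries. Insig1, at 78.56 CPM, and Stip1, at 234.2 CPM, were above them. The mean log2 CPM of KO 3 was 5.058 for cholesterol biosynthesis, above the other KO libraries, and 2.32 for stellate cells and fibroblasts, below them. In WT 2, Arhgap39 was at 26.79 CPM, Ccl2 at 50.27 CPM and Gpr183 at 4.268 CPM, each below the other WT libraries, and the total of 19445494 counts was above theirs. WT 3 had 1348 CPM of Alb, against 302 to 404.2 in the other WT libraries, and 1.918 CPM of Lrmda, below them. KO 1 had 6.678 CPM of Hbb-bs, above the other KO libraries.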

How the results depend on the processing

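Vsig4 kept its direction and call in all 29 alternatives, with log2 fold changes from -13.32 to -10.13 (-13.32 to -12.64 with each library left out) and adjusted p from 8.87e-172 to 0.00194. The covariate, leaving out 3 libraries, scaling to the Kupffer list, pairs left out of the block and set tests with the block were chosen after seeing the data. The 1 changed gene (0 higher, 1 lower) became 2 (1 higher, Gm42031) without filterByExpr, 66 (30 higher, 36 lower) in DESeq2, 2 (1 higher, Gm14541) in limma without a filter and 31 (17 higher, 14 lower) with array weights. With the replicate block it was 2220 (1425 higher, 795 lower), and with pair 1, 2, 3 or 4 left out of the block 207 (43 higher, 164 lower), 2 (1 higher), 1 (0 higher) and 2229 (1475 higher, 754 lower). Leaving out each library gave 1 to 2 genes (0 to 1 higher, 1 to 1 lower), the added gene being Gm42031 without KO 2 and Dynlt1b without KO 3. Genes near Vsig4 were 14 with the block and 0 to 0 with each library left out. The 27 lists became 0 with an estimated correlation and 0 with fry, 0 and 0 again with the block, 14 with the melanoma covariate and 15 without WT 1, WT 2 and KO 3. They were 22 to 28 with each library left out, and the block (26) changed no other list call than the erythroid. Lists called in either fit whose direction in camera turned had these medians with the covariate: T and NK 0.63, endothelium 0.083, scavenger 0.0043, lysosome 0.089, glycolysis -0.035 and mitochondrially encoded genes -0.22. Without the 3 libraries such lists had Kupffer 0.078, T and NK 0.76, endothelium 0.20, melanoma -0.29, complement 0.0014, scavenger 0.15, lysosome 0.20, LXR 0.081, iron 0.12, glycolysis -0.15, cell cycle 0.0036 and mitochondrially encoded genes -0.31. The cell cycle and mitochondrial medians kept their sign. Leaving out the 3 libraries removes the melanoma difference by selection, so these turns do not test lists that follow melanoma content. Other medians that changed sign were coinhibition 0.026 and 0.075 (call lost), and, in lists not called in any of these fits, costimulation 0.17 and 0.16, monocytes 0.049 and 0.016, B cells 0.032 and 0.067 and cholesterol -0.044 and -0.11, with the covariate and without the 3 libraries. Scaling to the Kupffer list moved the median of all genes by 0.72, and the lysosome median to 0.41, still below that shift. The cause was not tested. DESeq2 gave no adjusted p for 928 genes.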

Other observations

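The tests of explanations in this part were chosen after the results they bear on were seen, while the counts over other splits of the libraries were planned. The genes of this paragraph were also chosen after their values were seen. Gm42031, an unnamed gene on chromosome 8 (85852501 to 85858918, minus strand), had 0.211 ± 0.114 CPM in WT and 9.45 ± 5.84 CPM in KO (log2 fold change 5.51 ± 0.616, edgeR adjusted p = 0.0983, and 0.00898 with the replicate block). Tmem181b-ps, next to Dynlt1b on chromosome 17, had 28.2 ± 2.07 CPM in WT and 62.0 ± 21.4 CPM in KO, and Dynlt1-ps1 on chromosome 6 had 19.3 ± 0.795 CPM in WT and 29.5 ± 2.80 CPM in KO; such copies can share reads, so these levels are uncertain. Hsf3, which lies beside Vsig4 on the X chromosome (95349784 to 95499900, minus strand), had 2, 9, 11 and 2 counts in WT 1 to 4 and 28, 29, 22 and 26 counts in KO 1 to 4 (edgeR adjusted p = 0.492, and 0.0442 with the block). Gm49980 had 3.31 ± 1.28 CPM in WT and 9.46 ± 3.65 CPM in KO.

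Of the 27 called lists, 8 kept their call and direction with the block, with the melanoma covariate, without WT 1, WT 2 and KO 3, and without each library in turn. The 7 lower ones were the stellate, MHC class II, type I interferon, interferon gamma, chemokine, alternative activation and dissociation lists, and the ribosomal protein list was the higher one. Of these, the type I interferon and ribosomal medians were only -0.11 and 0.056 without the 3 libraries (camera adjusted p = 0.0358 and 0.0479), and none of the 8 was called with an estimated correlation or with fry, with or without the block. Relative to the Kupffer list, none of 9 lists tested differed between genotypes after adjustment (smallest exact permutation p = 0.114, adjusted p = 0.771, for the interferon gamma list, at -0.66 on the log2 scale). The type I interferon and stellate lists were at -0.21 and -0.26. MHC class I, MHC class II, NF-kB, chemokine, complement and dissociation lists were at 0.029, 0.080, 0.11, 0.083, 0.13 and 0.22. On this measure those lists fell no more than the Kupffer genes. Ifng itself had 76, 133, 31 and 35 counts in WT 1 to 4 and 65, 43, 36 and 9 counts in KO 1 to 4.

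RNA of melanoma cells in the sorted libraries may account for most of the 2220 genes called with the replicate block. Of the 2209 outside the melanoma list and Vsig4, 96.74% had the sign of their slope on melanoma content within genotypes, against 76.2% of the other tested genes, and their median change was 0.74 with the block (median SE 0.149), 0.71 without it (median SE 0.341), where the wider spread had already ended their calls, and 0.15 with the melanoma covariate in place of the block (quartiles 0.044 and 0.30, median SE 0.178). A lower share of Kupffer cells with every other cell type rising alike is argued against only if the pairing is right. With the block 15 of 85 genes in 8 lists of other cell types fell, in 5 lists, and 0 rose. All 10 melanoma genes rose. Of the 15 genes 7 were endothelial, and the endothelial median was 0.083 with the melanoma covariate. Blocked calls also depended on which pairs were in the fit. Medians decide less, being below 0 in 7 of the 8 lists but in 4 without WT 1, WT 2 and KO 3. No list parted from the melanoma list without the block (smallest exact permutation p = 0.0571). Whether genotype set the amount of melanoma RNA cannot be told apart from differences between livers or sorts, with 4 libraries per genotype (difference 1.65 on the log2 scale, exact permutation p = 0.2286). The sum was higher in KO in 4 of 4 pairs, but the pairing was read from these data and 4 pairs give no p under 0.125. The list was lower in KO without WT 1, WT 2 and KO 3 (median -0.29). That does not bear on the question, because those libraries had the least melanoma RNA of WT and the most of KO. The CD45 and Tim-4 gate should have removed melanoma cells, yet Dct had 1055 ± 1031 CPM in WT and 2257 ± 1576 CPM in KO; Mitf is the 1 gene of the list that macrophages also express, and free RNA and engulfed tumour material were not told apart.

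Lower interferon gamma response genes in KO are a hypothesis that these libraries leave open. Fewer T and NK cells as the whole cause were examined by setting the interferon gamma list against the T and NK list without Cd5. Relative to that list it differed by -0.88 on the log2 scale (exact permutation p = 0.02857), lower in KO in 4 of 4 pairs (-1.17 to -0.71). That decides only if response genes follow T and NK markers 1 to 1, which was not tested, so this cause stays open. Ifng itself was at 5.41, 7.47, 1.92 and 2.25 CPM in WT 1 to 4 and 3.62, 2.19, 1.99 and 0.472 CPM in KO 1 to 4. The gap between the genotypes in the difference of the 2 lists was only 0.0017. T and NK transcripts left in sorted cells may also not follow the T and NK cells of the liver, so that difference reaches no further than these libraries. Dilution of Kupffer RNA by melanoma RNA cannot be told apart from a change in the cells, as the genotypes overlapped in the difference from the Kupffer list (-0.66 on the log2 scale, exact permutation p = 0.1143) and the pairs differed in sign (0.31, -1.12, -0.23 and -1.60 in pairs 1 to 4, exact sign-flip permutation p = 0.375). An effect of genotype at a matched melanoma content may remain but cannot be told apart from chance here. With the melanoma covariate all 16 members had negative changes, and 0 of 16 passed adjusted over the list alone (smallest edgeR adjusted p = 0.0991). That linear term may not match melanoma content fully, so the changes left may include dilution.

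Other splits of the 8 libraries did not exclude chance for the counts without a block. For genes, 2 of 35 splits gave at least as many as the real one (1 gene, highest other 640). The split with 640 set numbers 1 and 2 of both genotypes against numbers 3 and 4, parting 0 pairs. Of the 35 splits it had the largest difference in the mean of the melanoma list (2.42 on the log2 scale, against 1.66 for the real split). It thus parted libraries low in melanoma content from those high in it. Among the other splits that part all 4 pairs, the highest was 0 genes. For lists, 2 of 35 splits gave as many (27, highest other 27). The lowest other was 7, so camera at its preset correlation called lists in every split. With the replicate block, 8 splits part the pairs, too few for a share under 0.05: 1 of 8 gave as many genes (real 2220, highest other 0) and 2 of 8 as many lists (real 26, highest other 29).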
